A study of Homo sapiens with 2 samples.

How the data were processed

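Total RNA was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. Any selection of polyadenylated RNA and the strand setting are not given in the sources used here. The data are 1 RNA-seq library of MCF7-derived breast cancer stem cells that overexpress SETD4 and 1 of the same kind of cells that overexpress GFP. Samples were assigned to these groups from the labels, and each column of the table was tied to its sample by the sample's title.

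The authors deposited 1 table with an FPKM value per gene and library, the ratio of those values, its log2, and a p-value and adjusted p-value. Bowtie2 2.2.9, TopHat2 2.1.1 and Cuffdiff 2.2.1 are named in the submitters' processing notes, without their roles. The FPKM values deposited by the authors are normalised for transcript length and library size, and any further scaling between the libraries is not given in the sources used here. The deposited fold column, a ratio, equals the SETD4 FPKM over the GFP FPKM, and the deposited log2 fold change differs from the log2 of that quotient by at most 0.00466. The p-value column in the authors' deposited table runs from 5e-05 to 0.05, so only genes at or under that limit are listed. Its adjusted p-values are those of a Benjamini-Hochberg adjustment over 14936 genes, since that number, of those searched, best turned their quotients into whole ranks (mean deviation 0.000353 over the smallest values, next best 0.0151). At a p-value of 0.04965 the rank was 1798, and 1721 genes are listed up to there; the other 77 were not analysed here. The submitters' processing notes name the mouse build mm9, whereas the table holds human Ensembl identifiers. Of the 1727 identifiers 1723 were found in GENCODE 29 (GRCh38), 1720 of them on the same chromosome. For 1122 the start (counted from 0) and end equal the GENCODE gene, and for 1637 the table's interval holds it. The coordinates were therefore read as GRCh38. Because the table's interval can span neighbouring genes (36034541 to 36126640 for SETD4), positions printed are those of GENCODE 29, counted from 1.

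The difference between the libraries was computed as log2((SETD4 FPKM + 1)/(GFP FPKM + 1)), so changes of low genes are understated. Genes with a mean of at least 1 FPKM (1632 of 1727) entered counts and lists. In the SETD4 library 2 genes are listed with FPKM values under 1e-10, and both fell under that minimum. The deposited values are not counts and no counts were recovered from them, so the read depth is unknown and no counting interval is given. With 1 library per group no test across libraries is possible, and the p-values quoted are those of the authors' deposited table, which compare 2 libraries. Adjustment over the members of a list alone was not made, because p-values are at hand only for listed genes.

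The following choices were made before the data were examined: the pseudocount, the minimum, the 2-fold size rule, the 37 gene lists, the main random-list comparison and the rule for named genes. That rule takes SETD4, the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 5 FPKM (small RNA names such as SNOR, MIR, RNU and RN7S left out), and for each list with a median of at least 0.3 in size its 4 most extreme members in that direction. For the lists on replication, mitosis, quiescence, H4 lysine 20 methylation, heterochromatin, stem cell and luminal markers it adds the 2 highest and 2 lowest members, and for the lists of other cell types the 3 most abundant ones. It names 104 genes. The design had assumed a table of all genes; with a table of selected genes, a list's median was compared with 10000 random lists of listed genes of the same size, drawn from the same 10 classes of mean expression. A list was said to stand apart under the 2.5 or over the 97.5 percentile, and lists with fewer than 5 listed members got values only. List members were matched by the table's symbol or by the current symbol of the identifier, which was found for 1719 of 1727. In a check on simulated data with 1632 genes, 6 of 100 unchanged lists of 15 genes were called, 68 of 100 lists shifted down by 1.5 on the log2 scale were called lower, and 100 of 100 shifted by 3.0. The check shuffled the observed log2 ratios over genes, so they were unrelated to expression, to length and to each other. Its rates therefore do not carry over to lists of related genes or of fewer members.

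Alternatives were pseudocounts of 0.1 and 5 FPKM, 3 other scalings (both libraries rescaled to an equal sum, upper quartiles made equal, log2 ratios centred on their median), no minimum and a minimum of 5 FPKM, thresholds of 1.5-fold and 4-fold, unmatched random lists and means over members. Rescaling to an equal sum raised the values of both libraries before the pseudocount of 1 was added. That setting therefore also acted as a smaller pseudocount. Added after the data were seen were random lists matched on transcript length, GC content and expression (1 of the 50 nearest genes per member, with lengths and GC content from GENCODE 29 transcripts) and the percentage of members that were higher. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.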

Results

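RNA-seq was used to compare breast cancer stem cells (BCSCs) that had been given extra SETD4 with BCSCs that had been given green fluorescent protein (GFP). SETD4 is a SET-domain protein lysine methyltransferase. The BCSCs were a sorted fraction of MCF7, an oestrogen receptor-positive human breast cancer cell line, and were infected with lentivirus. They were then kept for 2 weeks in low-attachment, tumorsphere-forming culture with 20 ng/ml epidermal growth factor and 20 ng/ml basic fibroblast growth factor. Each group held 1 library, so no value has a replicate error and no difference could be set against a spread between cultures. The table analysed listed 1727 genes with an expression level (FPKM, a fragment count scaled by transcript length and library size) in each library. All of these genes had an unadjusted p-value of at most 0.05 in the authors' deposited table, which therefore describes genes that differed and not the whole transcriptome. The listed FPKM values summed to 83452 in the GFP library and to 138655 in the SETD4 library. Read depth is unknown, because the values are not counts. Where a pair of FPKM values is given for a gene, the GFP library comes first.

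The first question was whether the targeted gene followed the labels. SETD4 (ENSG00000185917; GRCh38 chromosome 21, 36034541 to 36079389, minus strand, protein-coding) stood at 3.75 FPKM in the GFP library and 245 FPKM in the SETD4 library. This was 65.3-fold higher, and a log2 ratio of 5.69 with a pseudocount of 1 FPKM. The adjusted p for SETD4 in the authors' deposited table was 0.00996, the smallest value in that table, which other genes share. The comparison behind such p-values is between these 2 libraries, not between replicated conditions. The sequence of the vector insert and that of the endogenous transcript were not separated. The labels' protocols base the vector on the human SETD4 sequence but also name RNA of Artemia, a brine shrimp, as material for cloning. The 65.3-fold rise was measured at the human gene, which goes with a human insert. The insert sequence itself was not examined here.

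The second question was which other genes differed between BCSCs with SETD4 and BCSCs with GFP. Genes with a mean of at least 5 FPKM were ranked, with small RNA names such as RN7S left out. Besides SETD4, the 10 highest log2 ratios among them included those of PI3, LCN2, KRT81, AKR1B1 and the chemokine CXCL1, and the 10 lowest those of EGR1, FOS, CGA, SLC2A3 and SCD. PI3, the protease inhibitor elafin, stood at 48.9 FPKM with GFP and 487 FPKM with SETD4 (log2 ratio 3.29). LCN2, a lipocalin that binds iron siderophores, had 6.02 and 66.0 FPKM (3.25), and the hair keratin KRT81 had 5.71 and 61.9 FPKM (3.23). AKR1B1, aldose reductase, had 465 and 4231 FPKM (3.18). Keratin paralogs in the same cluster can share reads with KRT81. DLGAP1-AS1 (log2 ratio 3.21) is an antisense gene, and without a stated strand setting its reads cannot be told from those of its partner. The other 3 entries among the 10 highest were short structural RNAs. RMRP, the RNA of RNase MRP, was entered under both of its identifiers at the same position, with log2 ratios of 4.85 and 3.67, and a signal recognition particle RNA (Metazoa_SRP) had 3.39. In the authors' deposited table KRT81, CXCL1, DLGAP1-AS1 and both RMRP entries did not reach an adjusted p under 0.05, whereas the others among the 10 highest did.

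Among the 10 lowest genes, EGR1 (chromosome 5, 138465490 to 138469315) stood at 277 FPKM with GFP and 10.7 FPKM with SETD4, a log2 ratio of -4.57. CGA, the alpha subunit of the glycoprotein hormones, had 1087 and 122 FPKM (-3.14). SLC2A3, the glucose transporter GLUT3, had 334 and 45.6 FPKM (-2.85), and SCD, the stearoyl-CoA desaturase, had 858 and 129 FPKM (-2.73). TXNIP, an inhibitor of thioredoxin and of glucose uptake, had 253 and 36.1 FPKM (-2.78). AGR2, a secretory-pathway disulphide isomerase, had 22.02 and 1.89 FPKM (-2.99). The remaining members were FOS (-3.32), FOSB (-2.78), the kinase CDKL1 (-3.13) and the cytochrome oxidase isoform COX6B2 (-2.74). Of the 10 lowest, CDKL1 and FOSB did not reach an adjusted p under 0.05 in the authors' deposited table, whereas the others did.

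Of the 1632 listed genes with a mean of at least 1 FPKM, 505 were at least 2-fold higher and 544 at least 2-fold lower in the SETD4 library. That split rests on the deposited scaling. Rescaling both libraries to an equal sum gave 108 higher and 894 lower, upper quartile scaling gave 166 and 878, and centring on the median gave 738 and 56. These scalings moved the median log2 ratio of the listed genes by -0.82, -0.33 and 0.81, and were themselves computed on the listed genes alone. No named gene changed direction under any of them, and neither did any member of the lists below except 1 basal and mesenchymal gene under centring. This says little, because the genes were listed for having differed. The largest shift of the median, -0.817, was smaller in size than the smallest log2 ratio of a named gene (L3MBTL2, 0.819). Single genes moved by other amounts with the equal sum, such as SALL4 from -1.14 to -2.11. In the authors' deposited table, 38 higher and 78 lower genes had an adjusted p under 0.05.

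**Figure D1:**
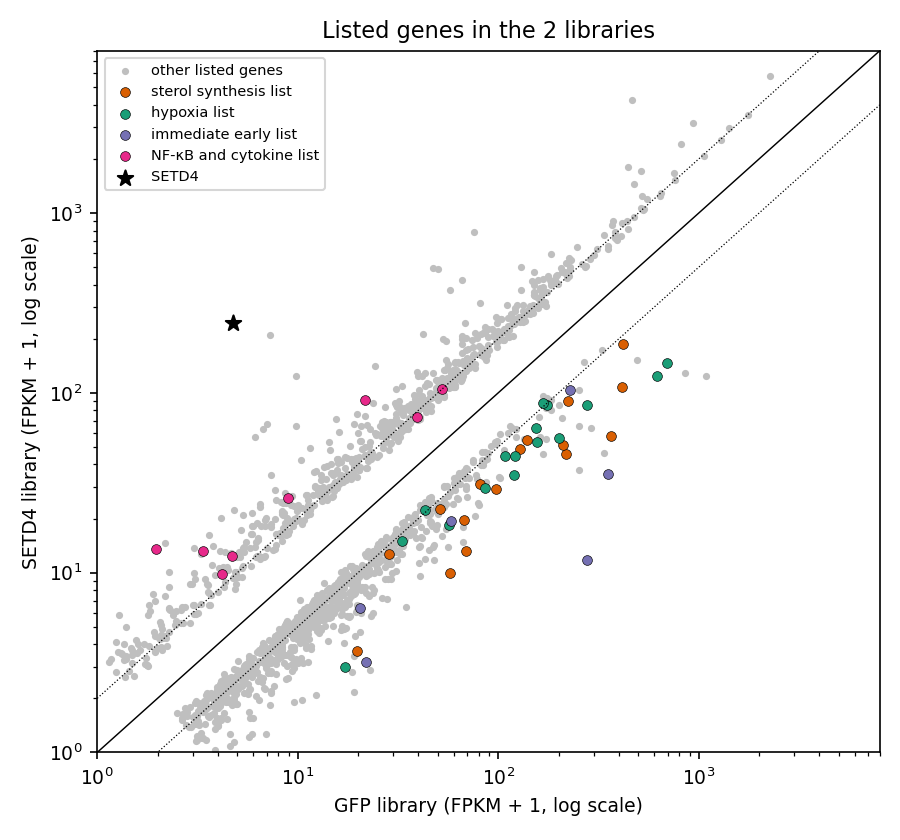
FPKM + 1 of each listed gene with a mean of at least 1 FPKM in the GFP library (x axis) and the SETD4 library (y axis), both on log scales; each point is 1 gene in 1 library per group, the solid line marks equality and the dotted lines a 2-fold difference. All sterol synthesis, hypoxia and immediate early genes lie below the line and all NF-κB and cytokine genes above it; the empty band along the line reflects that only genes with a p-value of at most 0.05 are listed.

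Genes were also grouped by 37 lists fixed before the data were examined, 1 of which holds SETD4 alone. Of these, 11 lists had at least 5 members in the table at a mean of 1 FPKM or more, and the median log2 ratio of each was placed among 10000 random lists of listed genes matched on expression. Medians of 5 lists lay among the lowest or highest 2.5% of the random lists. The percentile describes these 2 libraries, and it compares a list with other genes that already differed. The size of every list's median, including those given once below, depends on the scaling between the libraries.

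Sterol synthesis genes were lower together. Of the 23 genes of cholesterol synthesis and SREBP2 control, 16 were listed, whereas 12.04% of the genes the authors tested reached a p-value of 0.04965. All 16 were at least 2-fold lower in the SETD4 library, with a median log2 ratio of -1.77, below all 10000 random lists. After centring, 7 of the 16 were at least 2-fold lower and the median was -0.96, and with both libraries rescaled to an equal sum the median was -2.54. INSIG1, which holds SREBP in the endoplasmic reticulum and is itself a sterol-responsive gene, had 362 and 56.8 FPKM (-2.65). HMGCR, the rate-limiting enzyme of the pathway, had 68.5 and 12.2 FPKM (-2.40), the sterol carrier STARD4 56.3 and 8.93 FPKM (-2.53), and lanosterol synthase LSS 18.7 and 2.65 FPKM (-2.43). The authors' deposited table gave 8 of the 16 an adjusted p under 0.05.

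Hypoxia-inducible genes showed the same direction. Of 22 list members 16 were listed, and all 16 were lower, 14 of them at least 2-fold. The median log2 ratio was -1.54, below all 10000 random lists. Centring left 4 of the 16 at least 2-fold lower, with a median of -0.73, and the equal sum gave 16 and -2.29. CA9, a carbonic anhydrase induced by low oxygen, had 620 and 123 FPKM (-2.33), and NDRG1 had 696 and 145 FPKM (-2.25). P4HA1, a collagen prolyl hydroxylase, had 200.2 and 55.2 FPKM (-1.84), and PPFIA4 had 16.2 and 1.99 FPKM (-2.52). The authors' deposited table gave 6 of the 16 an adjusted p under 0.05. Only 2 of 19 glycolytic genes were listed, both lower: HK2, a hexokinase, at -1.75 and PFKFB4, a regulator of fructose 2,6-bisphosphate, at -1.82.

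Immediate early genes, which growth factors and stress switch on within minutes, had the lowest median of any list with at least 5 members. All 6 listed members of 24 were at least 2-fold lower, with a median log2 ratio of -2.24, below all 10000 random lists. Centring left 3 of the 6 at least 2-fold lower, with a median of -1.43, and the equal sum gave 6 and -3.24. After EGR1, FOS stood at 353 FPKM with GFP and 34.4 FPKM with SETD4, FOSB at 20.8 and 2.17, and ATF3 at 19.5 and 5.34 FPKM (-1.70). The authors' deposited table gave 4 of the 6 an adjusted p under 0.05.

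NF-κB target and cytokine genes were higher together. All 8 listed members of 21 were higher, 6 of them at least 2-fold, with a median log2 ratio of 1.46, and 1 of 10000 random lists reached it. With random lists matched on transcript length, GC content and expression, chosen after the data were seen, 31 of 10000 reached that median and 124 of 10000 had all members higher. With both libraries rescaled to an equal sum, 3 of the 8 were at least 2-fold higher and the median was 0.88, and after centring these were 8 and 2.27. CXCL1 had 0.971 and 12.5 FPKM (2.77), the neutrophil chemokine CXCL8 20.7 and 90.5 FPKM (2.08), IL6 2.36 and 12.2 FPKM (1.98) and IL1B 7.99 and 25.1 FPKM (1.54). The authors' deposited table gave 2 of the 8, CXCL8 and IL1B, an adjusted p under 0.05. Of 34 interferon-stimulated genes, 5 were listed at a mean of 1 FPKM or more and all 5 were higher, with OAS1 at 1.31, ISG15 at 1.24, IFI44 at 1.09 and OASL at 1.06 on the log2 scale. Their median of 1.09 stood at the 86.1 percentile, inside the range of random lists, and was 0.60 with the equal sum and 1.90 after centring. None of the 5 had an adjusted p under 0.05 in the authors' deposited table. IFI44L, listed under that level and named after its values were seen, was lower (1.11 and 0.181 FPKM).

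**Figure D2:**
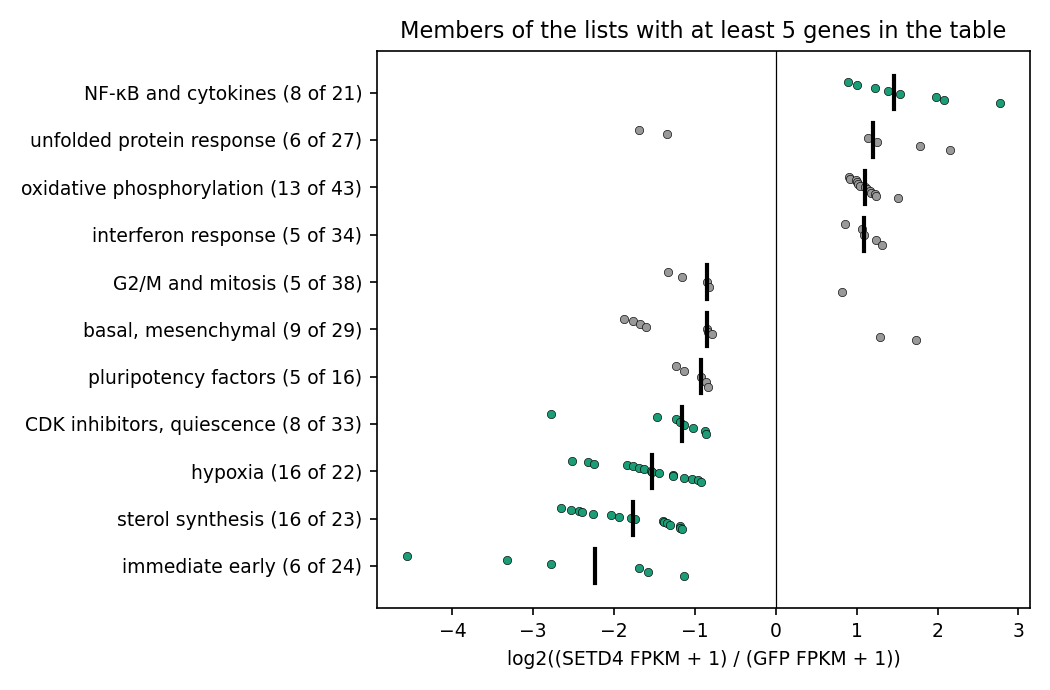
Log2 ratio of SETD4 to GFP (x axis, pseudocount of 1 FPKM) for each member of the 11 lists with at least 5 listed members (y axis, listed members of all members); each point is 1 gene, the bar is the list's median, and green marks lists whose median lay among the lowest or highest 2.5% of random lists. Sterol synthesis (median -1.77), hypoxia (-1.54), immediate early (-2.24) and CDK inhibitor genes (-1.16) lie wholly to the left of 0, and NF-κB and cytokine genes (1.46) wholly to the right. The pluripotency, oxidative phosphorylation and interferon lists, which are not green, also lie wholly on 1 side.

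SETD4 has been studied in connection with cell quiescence, so cell cycle lists were examined in turn. All 8 listed members of 33 in the list of CDK inhibitors and quiescence-linked factors were lower with SETD4, with a median log2 ratio of -1.16 at the 2.16 percentile (-0.35 after centring). TXNIP was the only one of the 8 with an adjusted p under 0.05 in the authors' deposited table. After TXNIP, the antiproliferative factor BTG2 had -1.47, the transcription factor KLF4 -1.23 and the BTG-family member TOB1 -1.19. FOXO3 had -0.88, and CDKN1B, which encodes the CDK inhibitor p27, had 62.5 and 33.9 FPKM (-0.86). The list left the lowest 2.5% with a pseudocount of 0.1 FPKM (percentile 3.95), with both libraries rescaled to an equal sum (3.76) and with unmatched random lists (2.5). It also left it with random lists matched on median transcript length, GC content and expression (2.54). The values of 2.5 and 2.54 lie at the limit itself. The list stayed in the lowest 2.5% with upper quartile scaling (1.63), a pseudocount of 5 FPKM (1.66) and no minimum (1.87). It also stayed there with a minimum of 5 FPKM (2.005) and with means over members (0.09). The equal sum setting also acted as a smaller pseudocount, so its percentile is no separate sign of dependence on scaling. Centring subtracts the same value from every log2 ratio, so the percentile of 2.16 could not change under it. Of 38 mitotic genes 5 were listed, with CENPE at -1.33, DLGAP5 at -1.16, BUB1 at -0.85, ECT2 at -0.83 and MYBL2 at 0.82, and the median of -0.85 stood at the 29.7 percentile. Among 35 DNA replication genes, POLD1 (1.16) and GINS3 (0.95) were listed, both higher. Of 19 G1/S regulators, E2F7 (-1.27), E2F8 (-0.98) and CDK6 (-0.86) were lower, and cyclin D1, CCND1, was higher (1.05).

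Each chromatin list had 3 listed members or fewer. Of 14 genes tied to histone H4 lysine 20 methylation, L3MBTL2, a reader of methylated lysine, was listed and was higher (0.82). Of 24 heterochromatin genes, SMCHD1, a chromatin protein of the inactive X chromosome, was listed and was lower (-1.21). Polycomb genes numbered 3 of 20 in the table, with PHC3 (-1.15) and SUZ12 (-0.90) lower and PHC2 (0.92), named after its value was seen, higher, and the list had a median of -0.90. All 3 listed histone genes of 26 were lower, namely HIST2H2BE (-1.36), H1F0 (-1.23) and HIST1H2AG (-1.10).

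Cell identity markers were listed in both directions. Of 19 breast cancer stem cell markers, the epithelial adhesion molecule EPCAM (2.70 and 0.618 FPKM, -1.19) and the aminopeptidase ANPEP (1.12) were listed, and the median of this pair, -0.03, had the opposite sign under centring (0.78). Pluripotency-linked factors were lower in 5 of 5 listed of 16, including SALL4 (-1.14), NES (-0.93) and SOX9 (-0.86) besides KLF4, with a median of -0.93 at the 51.1 percentile. Luminal and oestrogen receptor target genes were listed for 4 of 26, with AGR2, TFF1 (-1.54) and MYB (-0.85) lower and IGFBP4 (1.08) higher, and a median of -1.20. Of 29 basal and mesenchymal genes 9 were listed and 7 were lower (6 after centring on the median), among them the plasminogen activator inhibitor SERPINE1 (-1.88), the collagen cross-linking enzyme LOX (-1.77), SNAI1 (-1.68) and COL1A1 (-1.61). S100A4 (515 and 1719 FPKM, 1.74) and TWIST2 (1.29), named after their values were seen, were higher. The median of the 9 genes, -0.85, stood at the 32.9 percentile, but at -1.36 and the 0.92 percentile with a pseudocount of 0.1 FPKM. It was -2.02 (percentile 1.59) with both libraries rescaled to an equal sum, -1.61 (0.04) over the 7 members with a mean of at least 5 FPKM, and -0.04 (32.9) after centring. Here too the equal sum setting also acted as a smaller pseudocount, and centring could not change the percentile. The junction genes DSP (26.7 and 12.8 FPKM) and DSG2 (log2 ratio -0.91) were the listed ones of 21.

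Signalling lists had 3 listed members or fewer. In the Notch list of 19, HEY1 (-1.59), the DNA-binding effector RBPJ (-1.42) and NOTCH1 (-0.91) were lower. In the Wnt list of 26, the secreted inhibitor DKK1 (1.73), the co-receptor LRP5 (1.47) and CCND1 were higher. In the Hedgehog list of 13, PTCH1 (-1.10) and CDON (-0.92) were lower. Of 12 efflux transporter genes, ABCC3 was listed and was higher (1.36).

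Respiratory chain genes of the fixed list were higher wherever they were listed. All 13 listed members of its 43 nuclear-encoded subunits were higher, with UQCRQ at 146 and 417 FPKM and NDUFB7 at 1.24, NDUFS5 at 1.23 and ATP5G1 at 1.18 as log2 ratios. None of the 13 had an adjusted p under 0.05 in the authors' deposited table. Their median of 1.10 stood at the 74.5 percentile of random lists. It was 0.37 with both libraries rescaled to an equal sum, where no member was at least 2-fold higher, and 1.91 after centring. COX6B2, outside that list, was lower (17.7 and 1.80 FPKM). MT-CYB, on the mitochondrial genome, had 2262 and 5784 FPKM (1.35) and was the listed gene of 13. Cytosolic ribosomal proteins were listed for 3 of 51, with RPLP2 at 0.97, RPS2 at 0.89 and RPS15 at 0.85.

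Stress lists were mixed. Of 27 unfolded protein and integrated stress response genes 6 were listed. CHAC1, a glutathione-degrading enzyme (2.16), and the amino acid synthesis enzymes ASNS (1.78), PSAT1 (1.26) and PHGDH (1.14) were higher, whereas the other two, ATF3 among them, were lower, and the median of 1.20 stood at the 96.9 percentile (0.49 with the equal sum and 2.01 after centring). HSPB1 was the listed gene of 13 heat shock genes (1.10). Of 22 p53 targets 4 were listed, with BTG2, RRM2B (-1.08) and ZMAT3 (-1.07) lower and GDF15 (1.11), named after its value was seen, higher, and a median of -1.08. The BCL2 family and caspase list had 2 listed members of 23, named after their values were seen, BCL2 (-1.12) and BCL2L1 (1.27), and a median of 0.08, which was -0.90 with both libraries rescaled to an equal sum. ULK1, a kinase that starts autophagy, was the listed gene of 24 autophagy and lysosome genes (-1.26).

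Each list of markers of other cell types had 2 listed members or fewer at a mean of 1 FPKM or more. Of 13 leukocyte markers LAPTM5 was listed at a mean of 1 FPKM or more (7.53 and 20.5 FPKM, 1.34). Of 12 fibroblast markers, COL5A1 (65.5 and 17.1 FPKM, -1.88) and COL1A1 were listed at that level, both lower. Endothelial markers CDH5 (0.290 and 4.82 FPKM, 2.17) and PECAM1 (2.02 and 4.90 FPKM, 0.96) were higher, 2 of 10. Of 12 markers of HEK293T, the human embryonic kidney line used to package the virus, SALL4 was the one listed at that level, and was lower. Under that level, and named after their values were seen, the leukocyte marker CD14 (0.257 and 1.32 FPKM), the fibroblast marker DCN (0.222 and 0.803 FPKM) and the HEK293T marker UCHL1 (0.107 and 0.707 FPKM) were higher. Of 14 reference genes, the actin gene ACTB was listed and had 935 and 3177 FPKM (1.76).

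Direction went with transcript length across the table. Among the 163 genes whose longest annotated transcript had 254 to 1094 nucleotides, 87.1% were higher with SETD4, against 9.20% of the 163 genes of 8168 to 21103 nucleotides. Across 1630 genes, which are not independent replicates, Spearman's correlation of that length with the log2 ratio was -0.45, and that of GC content with the log2 ratio was 0.41. With the median length of a gene's transcripts it was -0.22. The median longest transcript of the listed respiratory chain genes was 874 nucleotides, that of the NF-κB list 1636, of the CDK inhibitor list 2762, of the immediate early list 3036, of the sterol list 3148 and of the hypoxia list 3510. Among genes of 2737 to 3520 nucleotides, 52.8% were higher. The small nuclear RNA RN7SK (56.2 and 374 FPKM) and the signal recognition particle RNA RN7SL1 (74.8 and 782 FPKM), chosen after their values were seen, were higher as well.

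**Figure D3:**
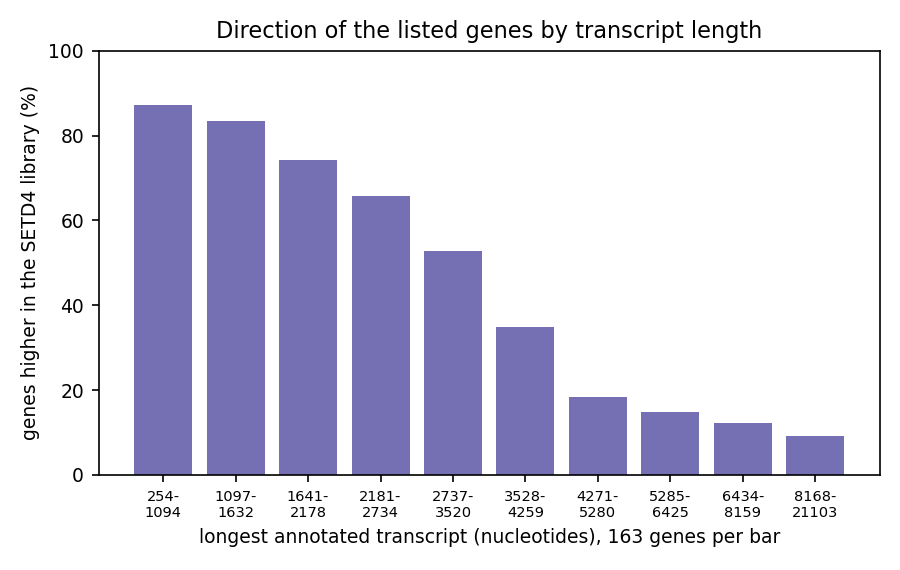
Percentage of listed genes that were higher in the SETD4 library (y axis) in 10 equal groups of 163 genes by the length of the longest annotated transcript (x axis, nucleotides); each bar is 1 group of genes from 1 library per condition, so there are no error bars. The percentage is 87.1% in the group of shortest transcripts and 9.20% in the group of longest ones.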

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

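The direction of SETD4, of the other named genes and of the 5 lists that stood apart was the same under every pseudocount and scaling tried. This was largely fixed in advance, because the genes were listed for having differed, and is no evidence of robustness. A pseudocount shared by both libraries cannot change a sign. The largest shift of the median under a scaling, -0.817, was smaller in size than any named log2 ratio (smallest 0.819, L3MBTL2). It is not a bound for single genes, which moved by other amounts with the equal sum. There SALL4 went from -1.14 to -2.11 and L3MBTL2 from 0.82 to 0.17. With a pseudocount of 5 FPKM, 326 genes were at least 2-fold higher and 170 lower, and SETD4 had a log2 ratio of 4.84. Random-list alternatives matched on transcript length and GC content were chosen after the data were seen. Rescaling to an equal sum gave 108 higher and 894 lower, upper quartile scaling 166 and 878, and centring on the median 56 lower, with SETD4 at 6.50. A 1.5-fold threshold gave 893 lower genes, and a 4-fold threshold 30 higher and 38 lower. The CDK inhibitor and quiescence list left the outer 2.5% with a pseudocount of 0.1 FPKM (median -1.19, percentile 3.95), with the libraries rescaled to an equal sum (-1.92, 3.76), with unmatched random lists (-1.16, 2.5) and with random lists matched on the median transcript length (-1.16, 2.54). That list stayed within the outer 2.5% under the other settings that compared it with random lists. The BCL2 family pair changed sign to -0.20, -0.90 and -0.24 with a pseudocount of 0.1 FPKM, rescaling to an equal sum and upper quartile scaling. The stem cell marker pair changed to 0.32, 0.78 and 1.12 with a pseudocount of 5 FPKM, centring and a minimum of 5 FPKM. In both cases the pair holds 1 gene in each direction, and the minimum of 5 FPKM leaves 1 of the stem cell markers. The pseudocount weighed less after rescaling to an equal sum, which raised the values. Percentiles under that setting are therefore not separate from those with the pseudocount of 0.1 FPKM. The cause of the other changes was not tested. Outside the main comparison, the basal and mesenchymal list stood apart under 4 alternatives: a pseudocount of 0.1 FPKM (median -1.36, percentile 0.92), rescaling to an equal sum (-2.02, 1.59), a minimum of 5 FPKM (-1.61, 0.04) and the percentage of members higher in lists matched on length, GC content and expression (22.2%, 0.71). The stress response list did so with a pseudocount of 5 FPKM (percentile 98.6), no minimum (97.7) and unmatched lists (97.7), the respiratory chain list with unmatched lists (98.4), and the interferon list with means over members (97.54) and the percentage of members higher (98.7). The number of lists that stood apart was between 4 and 6 under all alternatives. No library could be left out, because each group has 1. No paired analysis was possible because the groups have 1 library each and the labels give no replicate numbers. Depth is unknown, so no limit of detection can be given for low genes.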

Other observations

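The families in this paragraph, the scaling tests and the statement on cultures were chosen after the results were seen; random lists matched on length, GC content and expression were added after the table was seen but before their outcome was. All 28 listed mitochondrial ribosomal protein genes, of 78 annotated, were higher in the SETD4 library, with a median log2 ratio of 1.11. Random lists matched on transcript length, GC content and expression had a median of 22 higher members, and 3 of 10000 had 28, while the family's median stood at the 96.7 percentile of those lists, inside the range used for the fixed lists. All 14 listed proteasome subunit genes of 44 were higher (median 1.11), which 327 of 10000 matched lists equalled, and so were all 15 complex I genes of 39 (median 1.07), which 1396 equalled. The 6 listed S100 genes of 22 were all higher, which 4527 of 10000 matched lists equalled, and their median of 1.39 stood at the 97.7 percentile of those lists. With both libraries rescaled to an equal sum, the medians were 0.40 for the mitochondrial ribosomal, 0.39 for the proteasome, 0.34 for the complex I and 0.82 for the S100 genes.

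Zinc finger genes named ZNF were lower in 28 of 34 listed of 514 (median log2 ratio -0.95, and 24 of 34 after centring on the median), and 3918 of 10000 matched lists had as many lower members. Collagen genes were lower in 5 of 6 listed of 45 (median -1.07, and -0.26 after centring), and 3903 of 10000 matched lists had as many.

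Short transcripts were mostly higher and long ones mostly lower in the SETD4 library. By the longest annotated transcript, GC content alone is argued against as the whole cause. The Spearman correlation of that length and log2 ratio across genes was -0.33 given GC content, though GC content kept a correlation of 0.27 given that length. With the median transcript length the correlation was -0.22. It was not computed given GC content, so GC content stays open by that measure. The correlations that follow also used the longest transcript. The fixed lists and the ribosomal, mitochondrial, proteasome and zinc finger families are argued against as the whole cause. Among the 1371 genes outside all of them the correlation was -0.44. Other families, such as S100 and collagen genes outside the lists, were not left out and stay open. The length correction of very short transcripts is argued against as the whole cause by -0.28 among the 1199 genes of at least 2000 nucleotides. A length-dependent difference in RNA integrity or library preparation predicted the trend outside the lists and families left out, and the same -0.44 goes with it. An effect of SETD4 on transcripts of different length stays open and was not tested, as 1 library per group separates neither from the other.

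The sterol synthesis, hypoxia and immediate early lists were lower in the SETD4 library. Transcript length, GC content and expression level are argued against as the whole cause: the medians stood at the 0, 0.01 and 0 percentiles of lists matched on all of these, for sterol synthesis, hypoxia and immediate early genes in that order. Scaling of the libraries stays open as a part of the size of these medians: the highest under the 3 scalings tried were -0.96, -0.73 and -1.43, in that order, but the shifts were smaller than the medians from the start and were computed on genes listed because they differed. A difference between the 2 cultures other than SETD4, such as sphere size, oxygen, medium age or handling at harvest, cannot be told apart from an effect of SETD4, because there is 1 library per group. A candidate explanation by SETD4 is therefore a hypothesis that replicate cultures would test.

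All 8 listed CDK inhibitor and quiescence-linked genes were lower in the SETD4 library. Transcript length, GC content and expression level cannot be told apart from a change of the list itself: its median stood at the 1.79 percentile of lists matched on the longest transcript, GC content and expression, but at 2.54 with the median transcript length. By direction alone, 9 of 10000 lists matched on the longest transcript had no higher member. An effect of SETD4 and a difference between the cultures stay open, and neither was tested.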
